A study of Oryza sativa with 16 samples.

How the data were processed

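Total RNA from shoot apical meristems of rice (Oryza sativa) was sequenced by the authors in 16 libraries, 2 for each of 8 groups (WT and d1 at stages 1, 2, 4 and 7). The labels describe plants of 3 months that grew for 100 days and about 40 M reads of 150 bases per library. They do not define the stage numbers. Groups were taken from the sample labels alone, and 0 samples were left unassigned.

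The deposited values are FPKM (fragments scaled by transcript length and library total), a unit that was inferred from the tools named and from the values, since the table does not state it. Per the submitters' processing notes, the authors used FastQC, Trimmomatic, TopHat2, Cufflinks and Cuffdiff with the genome build IRGSP-1.0, with no versions given. Each column is named for a genotype and stage, so the authors had combined the 2 libraries of a group into 1 value before deposit. How the columns were scaled to each other is not given in the sources used here. FPKM values hold no counts, the depth behind a value is unknown, and no interval or floor can be given. A gene at exactly 0 is therefore described only as listed at 0. Reads shared between near-identical genes may have been split by the authors' estimation, and overlapping genes cannot be told apart here.

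The table held 34302 rows, of which 4802 were 0 in all 8 columns and 54 joined several names. In 1 row a joined part was a gene name, and 1 identifier was on more than 1 row. Genes with at least 1 FPKM in at least 2 columns were kept, which left 19757. Values were analysed as log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes.

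The planned tests between libraries could not be made from combined values, and the fallback written before the data were examined was used. The genotype comparison was a limma fit (version 3.58.1, R 4.3.3; eBayes with trend) on the 8 columns, with stage as a block and Benjamini-Hochberg adjustment. It has 3 residual degrees of freedom, to which eBayes added 2.54 prior ones. The SE is therefore moderated: the spread of each gene is drawn toward that of genes of like abundance. The SE and p-values of this fit rest on how far the d1 minus WT difference varies between the 4 stages, moderated in this way. They do not measure the spread between plants or libraries, so they describe the authors' values. At single stages, and between stages 7 and 1 in each genotype, genes with an absolute log2 difference of at least 1 were counted with no test. The stage contrast over both genotypes comes from the same fit and was added after the layout of the table was seen. Whether the genotype difference varies with stage was not tested. Values were simulated for the comparison of d1 with WT over the 4 stages (19757 genes, 200 of them changed, 10 runs). The fit recovered 41.4% of changes of 0.5, 76.8% of 1, 93.2% of 2 and 97.8% of 3 on the log2 scale. It made 6.5 false calls per run on average. These shares need not carry over to the data, where a difference that varies in size between stages has a wider SE. OS09G0109600, for example, was not called with a log2 difference of -3.39 (adjusted p = 0.064, limma).

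Apart from 1 row with a gene name among its joined parts, the files used here do not pair the identifiers with gene names. The NCBI gene table used (assembly ASM3414082v1, a build other than the authors') lists names but none of these identifiers, so 0 identifiers could be matched to a name directly. Genes are therefore given by identifier, with at most 2 that rose and 2 that fell per comparison, those with the largest change past the threshold and, between genotypes, the same sign at all 4 stages. The exception is RGA1, the mutated gene, whose identifier was written down from general knowledge beforehand. The rule fixed beforehand also named list members, and these are given by their values only, because no table pairs them with a name. Where a list member is singled out, it is the most abundant or the most changed of its list, or a member chosen after its values were seen.

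Gene lists were made of 241 identifiers written down from general knowledge for named genes, 65 of them beforehand and the others later, before their values were looked at. A member was used only where its identifier was in the table and the NCBI table had the gene's name on the same chromosome, at a place in the same order as the identifiers. This order held for 169 of 169 identifiers that could be checked; 90 of these were not analysed here, so each list covers only a part of the genes written down for it, and its counts describe that part. Names of 64 were not found and of 8 only on another chromosome, and these were not used in the lists, among them 3 G protein identifiers that are in the table. That left 79 members, 18 of them written down beforehand, and 66 passed the filter. All tested members of the MADS-box and G protein lists were written down beforehand, as were 5 of the 7 panicle branching members, and 1 each of the gibberellin, brassinosteroid and KNOX, BELL and WOX members. The photosynthesis list, of 12 tested identifiers, also used those whose name the NCBI table does not list, and 0 of them was written down beforehand. The grain size, clock, abiotic stress, floral organ and small RNA lists were added later. Planned lists defined by product descriptions (ribosomal proteins, histones, heat shock, cell wall, vascular tissue) are void, since no table of descriptions was used here, and no strigolactone member was analysed here. For lists of at least 3 tested members, the median log2 difference was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean expression, with no p-value.

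Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, quantile normalization, array weights, an absolute log2 change of at least 1, each stage left out in turn, another fold threshold and a filter of at least 5 FPKM in a group. Median scaling of the tested fit and leaving out chromosome 5 were chosen after seeing the data.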

Results

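RNA was sequenced from rice shoot apical meristems, the growing tips that turn into panicles at flowering. Wild type (WT) plants were compared with the d1 mutant, which carries the d1-1 allele of RGA1, the gene of the heterotrimeric G protein alpha subunit. Meristems were taken at stages labelled 1, 2, 4 and 7 of panicle initiation, with 2 libraries for each of the 8 groups and 16 libraries in all. The authors' table gives 1 FPKM value per gene for each group, so the values below are the authors' combined values and carry no SD or n. The depth behind them is unknown, although the labels state about 40 M reads per library. The summed FPKM per column lay between 621238 and 670519 and was higher in d1 than in WT at each stage. In a column, 18037 to 18929 of the 34302 rows reached 1 FPKM. Across the 19757 genes that were tested, WT and d1 at the same stage correlated with Pearson's r of 0.978 to 0.984. Stage 1 and stage 7 correlated with r of 0.933 in WT and 0.930 in d1. Genes are not independent replicates, so these correlations describe the columns only.

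The transcript of the mutated gene was examined first. RGA1 (OS05G0333200, chromosome 5; the identifier is from general knowledge, as no table used here pairs it with the name) had 27.5, 29.6, 30.3 and 29.8 FPKM in WT at stages 1, 2, 4 and 7. In d1 the values were 22.0, 20.9, 23.6 and 24.1 FPKM. The mutant value was lower at 4 of 4 stages, with a mean of 22.6 against 29.3 FPKM, a ratio of 0.773. The difference was -0.36 ± 0.05 (log2, moderated SE from the fit over the 4 stage pairs). Its adjusted p of 0.064 (limma, Benjamini-Hochberg over all tested genes) did not pass 0.05. RGA1 was past the threshold when adjusted over the list alone, the list being the 3 G protein subunits that were matched. It was also past it over all genes under 2 alternative settings, with adjusted p of 0.047 when genes needed a mean of at least 5 FPKM and 0.044 with array weights; over all alternatives that tested it, the adjusted p ran from 0.044 to 0.30. The most abundant other subunit on that list had 48.7 to 53.2 FPKM across WT and d1, with a difference of 0.00 ± 0.04 (adjusted p = 0.96, limma). The remaining subunit had low values, 0.59 to 3.48 FPKM. Its difference of 0.25 ± 0.11 had an adjusted p of 0.23.

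**Figure D1:**
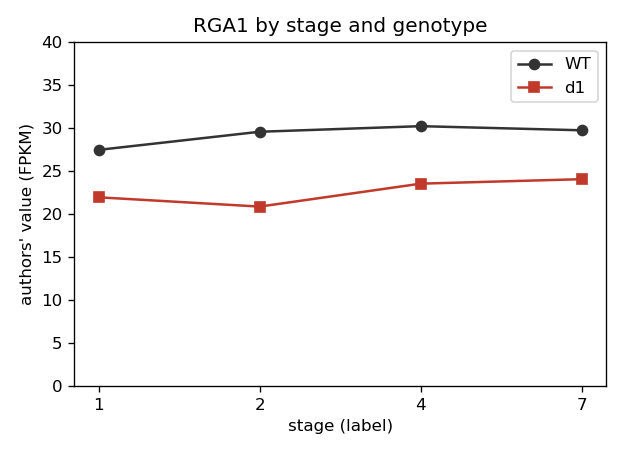
RGA1 by stage and genotype. The vertical axis is the authors' FPKM value and the horizontal axis the stage label; circles are WT and squares are d1, with 1 combined value per point and no error bar. The 4 WT values lie between 27.5 and 30.3 FPKM and the 4 d1 values between 20.9 and 24.1 FPKM.

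The next comparison asked which genes differed between d1 and WT in the same way over the 4 stages. At an adjusted p under 0.05, 31 genes were higher and 17 were lower in d1, of 19757 tested (limma on log2(FPKM + 1), stage as block). With the columns scaled to the same median, 12 were higher and 9 lower, so the lean toward higher values in d1 depended on scaling. At an unadjusted p under 0.05 there were 4674 genes, where chance gives 988. Each of the 48 called genes had the same sign at 4 of 4 stages, which the test all but requires. A difference that changes sign between stages has a wide SE and could hardly pass, so this is no separate support. Among the 31 higher genes, the largest increases belonged to those that the table lists at or near 0 in WT. OS05G0230501 (chromosome 5) was listed at 0 in all 4 WT columns and at 54.6, 45.0, 33.4 and 47.6 FPKM in d1 (adjusted p = 0.00029). OS05G0281400 (chromosome 5) was listed at 0 in WT except for 0.043 FPKM at stage 7, and at 14.6, 12.2, 12.1 and 10.2 FPKM in d1 (adjusted p = 0.00071). Among the 17 lower genes, the largest decrease was that of OS10G0492900 (chromosome 10). It had 3.79, 4.30, 27.2 and 34.7 FPKM in WT and 0.51, 0.97, 6.63 and 5.53 FPKM in d1. Its log2 difference was -1.86 ± 0.17 (adjusted p = 0.042). OS05G0206200 (chromosome 5) had 1.85, 1.63, 2.65 and 1.95 FPKM in WT and at most 0.058 FPKM in d1 (log2 difference -1.56 ± 0.11, adjusted p = 0.033). Neither decrease passed the threshold without a filter on low values (adjusted p of 0.12 and 0.051) or with any 1 stage left out (0.073 to 0.27). Some genes that were not called had a larger mean decrease. Among them were OS09G0109600 (log2 difference -3.39, adjusted p = 0.064, limma) and OS03G0723400 (-2.81, adjusted p = 0.079, limma).

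Chromosome 5, where RGA1 lies, held 10 of the 48 genes. This was 0.609% of its 1643 tested genes, against 0.210% of the 18114 genes on other chromosomes (Fisher's exact test, two-sided, p = 0.0054). When genes needed a mean of at least 5 FPKM, 28 genes were called on chromosome 5 and 287 elsewhere, with no excess (odds ratio 1.06, Fisher's exact p = 0.76). Of the 48 genes, 8 on chromosome 5 and 36 elsewhere had such a mean. Among genes with such a mean, the odds ratio was 2.43 for those of the 48 genes (Fisher's exact p = 0.028) and 4.86 for the refit calls with an absolute log2 change of at least 1 (Fisher's exact p = 0.019). Of the 10 genes, 5 were higher and 5 were lower in d1. By identifier number, 9 of the 10 preceded RGA1 and 1 followed it, where 631 and 1011 genes were tested (Fisher's exact test, two-sided, p = 0.0012). The tests on chromosome 5 were chosen after the calls had been seen, except the refit with a mean of at least 5 FPKM. Most of the 48 differences were modest, with a median absolute log2 change of 0.63, and 12 genes reached 1. The count itself was sensitive to the settings: it was 7 without a filter on low values, 21 after median scaling, 315 with a mean of at least 5 FPKM and 401 with array weights. Leaving out stage 1, 2, 4 or 7 left 5, 5, 4 and 5 genes, all of them among the 48.

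**Figure D2:**
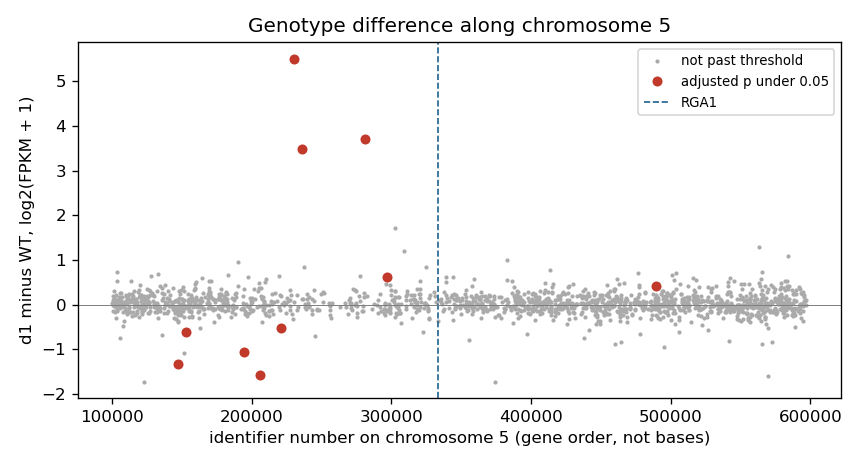
Genotype difference along chromosome 5. Each point is a tested gene, placed by the number in its identifier, which follows gene order and not bases; the vertical axis is d1 minus WT in log2(FPKM + 1) averaged over the 4 stages. Filled red points are the 10 genes with adjusted p under 0.05, and 9 of them lie to the left of the dashed line that marks RGA1.

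Genes of panicle development and hormone pathways were then compared between d1 and WT by list. The tested lists held 66 members, and 0 of them passed the threshold over all genes (limma). An unadjusted p under 0.05 (limma) was found for 17 of the 66, where 23.7% of all 19757 tested genes had one. By sign alone, 14 members were higher and 7 were lower in d1 at all 4 stages. The share of all tested genes with the same sign at all 4 stages is not given here. For the panicle branching and spikelet meristem list (7 members), the differences ran from -0.16 to 0.41, and the smallest adjusted p was 0.080. The most abundant member of that list had 1917, 1428, 977 and 177 FPKM in WT and 1635, 1558, 772 and 153 FPKM in d1. The 5 floral MADS-box transcription factors differed by -0.07 to 0.26, and the 3 meristem homeobox members of the KNOX, BELL and WOX list by -0.06 to 0.23. Those 3 members were all written down as KNOX genes, so results of that list cover no BELL or WOX gene. The most abundant homeobox member had 354 FPKM in both genotypes at stage 1. Differences were -0.20 to 0.15 for 5 gibberellin genes, -0.11 to 0.19 for 7 brassinosteroid genes, -0.06 to 0.12 for 5 cytokinin genes and -0.32 to 0.17 for 4 auxin genes. The 6 DNA replication and cell division members differed by 0.06 to 0.21. The 4 meiosis and tapetum members differed by -0.08 to 0.36 and the 4 defence members by -0.39 to 0.79.

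Adjusted over the list alone, 1 member passed in each of the G protein, brassinosteroid, KNOX, BELL and WOX, panicle branching and defence lists. No member passed in that way in the MADS-box, gibberellin, cytokinin, auxin, DNA replication or meiosis lists, where 1, 2, 0, 2, 1 and 2 members had an unadjusted p under 0.05. Set against 10000 random lists of the same size and expression, the median differences of these 11 lists lay between percentile 25.8 (KNOX, BELL and WOX) and percentile 95.5 (meiosis and tapetum). A list of 3 grain size and growth genes, chosen later than the others, had its median of -0.19 at percentile 1.24, and 2 of its members passed when adjusted over the list alone. The 3 circadian clock members, also added, had a median of -0.11 at percentile 5.89. The 3 abiotic stress members, added likewise, had a median of -0.10 at percentile 11.7. At single stages, apart from the photosynthesis list, the medians outside the central 95% were those of the meiosis list at stages 4 and 7 (percentiles 99.6 and 98.8), the panicle branching list at stage 4 (98.6) and the MADS-box list at stage 7 (97.6). So were those of the clock list at stages 2 and 4 (0.61 and 1.55) and the grain size list at stages 1 and 2 (2.19 and 1.17). These come from 14 lists at 4 stages. By construction 5% of the random lists lie outside, but their genes were matched on expression alone. How often a list of genes that move together would lie outside by chance is not known. The 3 floral transition members held in the table never exceeded 1.01 FPKM and were not tested.

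Differences at single stages could only be described, since each group has 1 value. A log2 difference of at least 1 was seen for 301 genes higher and 90 lower in d1 at stage 1, and for 338 higher and 216 lower at stage 2. At stage 4 there were 142 higher and 189 lower, and at stage 7 there were 117 higher and 303 lower. These genes made up 1.68% to 2.80% of those tested, and the median difference over all tested genes was at most 0.02 at any stage. At a mean of at least 5 FPKM the 4 counts were 157, 215, 129 and 178, and with a pseudocount of 0.1 they were 992, 1201, 806 and 898. Whether any gene's difference varied between stages was not tested, because no library values were at hand. Across genes, the differences at stages 4 and 7 correlated with r of 0.51, those at stages 1 and 4 with 0.37 and those at stages 1 and 2 with 0.31. Stages 2 and 7 gave r of 0.01. The 4 stages share no column, so these values are not raised by shared controls. A difference of at least 1 in the same direction at all 4 stages was found for 7 genes higher and 11 genes lower in d1, and 8 of these 18 genes lie on chromosome 5. When the sign of the difference was turned for whole stages, the highest of the 7 other sign patterns gave 6 genes.

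Transcripts of photosynthesis, which are abundant in leaves, varied between the columns beside these counts. The 12 tested identifiers of a photosynthesis list had a median log2(FPKM + 1) of 1.80, 3.33, 1.32 and 2.62 in WT at stages 1, 2, 4 and 7. In d1 the medians were 3.91, 2.62, 2.35 and 2.24. The median d1 minus WT difference of the list was 1.89 at stage 1 and -0.75 at stage 2, with all 12 members higher in d1 at stage 1 and 11 of 12 lower at stage 2. It was 0.53 at stage 4 and -0.21 at stage 7. Against random lists of the same size and expression, the percentiles were 100 at stage 1, 0 at stage 2, 100 at stage 4 and 1.89 at stage 7. Over the 4 stages 0 of the 12 members passed the threshold (limma, 0 had an unadjusted p under 0.05), with a median of 0.42 at percentile 100. By sign, 10 members were higher and 2 were lower in d1. The 2 lower members (-0.09 and -0.36) were the only ones whose name had been matched, so the positive median rests on identifiers that were not checked. The most abundant member reached 34.1 FPKM, in WT at stage 2.

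The stage series was compared between its ends. In WT, 1556 genes were higher and 552 lower at stage 7 than at stage 1 by a log2 difference of at least 1, and in d1 the counts were 1229 and 840. After quantile normalization the WT split was 1212 higher and 751 lower. Both genotypes shared 1367 genes with such a change in the same direction and 40 in opposite directions, where independent lists would share 120 in the same direction. Across genes, the change in WT correlated with that in d1 (Pearson's r of 0.782, Spearman's rho of 0.678). Step by step, 504, 910 and 655 genes differed by at least 1 from stage 1 to 2, 2 to 4 and 4 to 7 in WT. The d1 counts were 464, 1055 and 709.

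Over both genotypes, 2739 genes rose and 2800 fell between stage 1 and stage 7 (limma, adjusted p under 0.05), together 28.0% of those tested. With the columns scaled to the same median, 2356 rose and 3300 fell. In the fit without that scaling, 1153 of the genes past the threshold were higher and 529 lower at stage 7 by an absolute log2 change of at least 1. The largest rise was that of OS03G0245300, from 0.066 to 283 FPKM in WT and from 1.41 to 658 FPKM in d1 (log2 change 8.08 ± 0.18, adjusted p = 0.00015). OS10G0150400 rose from 0.33 to 138 FPKM in WT and from 0.62 to 207 FPKM in d1 (6.85 ± 0.44, adjusted p = 0.00073). OS04G0522500 fell from 243 to 1.98 FPKM in WT and from 286 to 2.17 FPKM in d1 (-6.43 ± 0.10, adjusted p = 8.1e-05). OS07G0512250 fell from 98.0 to 1.29 FPKM in WT and from 88.02 to 1.20 FPKM in d1 (-5.39 ± 0.22, adjusted p = 0.00027).

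Of the 66 list members, 19 rose, 18 fell and 29 did not pass. Among the 5 genes of the floral and inflorescence MADS-box list, 4 rose and 1 fell. Of those that rose, 3 were under 1 FPKM at stages 1, 2 and 4 in both genotypes. They reached 4.66 to 49.8 FPKM in WT and 5.99 to 43.1 FPKM in d1 at stage 7. The most abundant of the 3 had 0.15 FPKM at stage 4 and 49.8 FPKM at stage 7 in WT (4.82 ± 0.12 from stage 1 to 7). The fourth gene that rose was expressed from stage 1, at 16.8, 21.3, 43.1 and 32.6 FPKM in WT (0.83 ± 0.11). The gene that fell went from 4.10 to 0.10 FPKM in WT and from 5.07 to 0.43 FPKM in d1 (-2.15 ± 0.13). The median change of the list, 2.64, was at percentile 100 of random lists of the same size and expression.

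Genes of panicle branching and spikelet meristems moved mostly the other way, with 5 that fell and 2 that rose among 7. The most abundant member, at 1917 FPKM in WT at stage 1, fell to 177 FPKM at stage 7, and in d1 from 1635 to 153 FPKM (-3.42 ± 0.12, adjusted p = 0.00023). A second member fell from 343 to 25.5 FPKM in WT and from 378 to 38.7 FPKM in d1 (-3.47 ± 0.11). The steepest fall in this list was from 94.8 through 34.4 and 5.35 to 3.38 FPKM in WT, with 98.2, 44.1, 10.4 and 4.35 FPKM in d1 (-4.33 ± 0.18). A member listed at 0 in both genotypes at stage 1 was at 3.13 FPKM in WT and 4.04 FPKM in d1 at stage 4, and at 2.90 and 3.60 FPKM at stage 7 (2.08 ± 0.14). The median change of the list was -1.53, below all 10000 random lists.

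The meristem homeobox list, of which only KNOX genes were tested, had 2 members that fell and 1 that did not pass. Its most abundant member had 354, 468, 476 and 234 FPKM in WT and 354, 441, 478 and 251 FPKM in d1 (-0.54 ± 0.07, adjusted p = 0.0046). The list median of -0.54 was at percentile 2.29. Of the 5 cytokinin members, 3 fell and 1 rose, with a median of -0.53 at percentile 0.33. The cytokinin member with the largest change fell from 22.3 to 4.79 FPKM in WT and from 22.9 to 4.92 FPKM in d1 (-2.01 ± 0.18). Another peaked at stage 4, with 33.7 FPKM in WT and 32.1 FPKM in d1, and had 8.37 and 8.71 FPKM at stage 7. Of 6 DNA replication and cell division members, 4 rose, by 0.25 to 0.45, and the list median of 0.26 was at percentile 99.4. Of 4 defence members, 2 rose and 2 did not pass, with a median of 0.40 at percentile 97.6. The larger rise, from 0.20 to 29.4 FPKM in WT and from 0.12 to 138 FPKM in d1, was the largest of any list member (5.81 ± 0.52, adjusted p = 0.0017).

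The gibberellin, brassinosteroid, auxin, meiosis and G protein lists had medians inside the central 95% of random lists. Among 5 gibberellin genes, 2 rose, 1 fell and 2 did not pass. The gene that fell went from 37.4 to 14.7 FPKM in WT (-1.43 ± 0.10), and the larger rise was from 7.50 to 19.2 FPKM (1.20 ± 0.08). Among 7 brassinosteroid genes, 1 rose, 2 fell and 4 did not pass, the most abundant falling from 216 to 140 FPKM in WT (-0.57 ± 0.06). In the auxin list 1 of 4 members fell, in the meiosis and tapetum list 1 of 4 fell, and of the 3 matched G protein subunits 1 rose (1.26 ± 0.15), the subunit with the lowest values. The added lists gave 1 fall among 3 grain size and growth genes, 1 rise among 3 abiotic stress genes and 0 calls among 3 clock genes (limma; 0 had an unadjusted p under 0.05). The single floral organ identity gene rose, from 20.4 to 103 FPKM in WT with 2.91 FPKM at stage 4. The single small RNA pathway gene fell from 467 to 370 FPKM in WT. No photosynthesis identifier passed (limma, 0 of 12 at an unadjusted p under 0.05), and the list median of -0.32 was at percentile 0.39. By sign, 5 identifiers were higher and 7 lower at stage 7. They move together and the random lists were matched on expression alone, so that percentile does not show how rare the shift is.

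**Figure D3:**
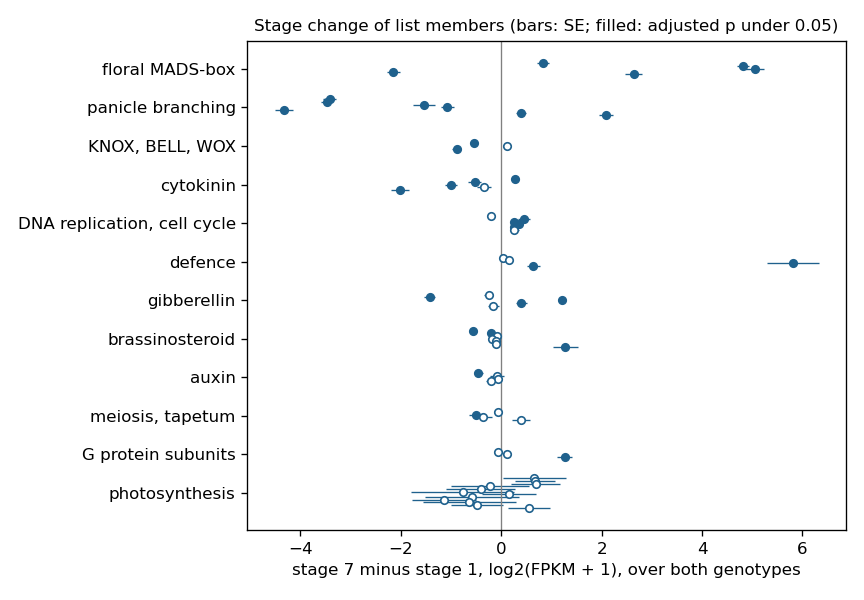
Change from stage 1 to stage 7 of list members over both genotypes. Each point is a list member, with the log2(FPKM + 1) change on the horizontal axis and its SE as a bar; filled points have an adjusted p under 0.05 (limma). The floral MADS-box list has 4 filled points to the right and 1 to the left of 0, and the panicle branching list 2 to the right and 5 to the left.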

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

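Median scaling of the fit, leaving out chromosome 5 and all alternatives of the stage contrast over both genotypes were chosen after seeing the data. The count of genes that differed between d1 and WT over the 4 stages was 48. It was 47 with a pseudocount of 0.1 and 58 after quantile normalization, with 45 and 43 of the 48 shared. It was 7 with no filter on low values, where 29500 genes were tested, 315 with a mean of at least 5 FPKM, where 13754 were tested, 401 with array weights, 12 with an absolute log2 change of at least 1, 21 after median scaling and 31 without chromosome 5. Leaving out stage 1, 2, 4 or 7 gave 5, 5, 4 and 5 genes with 3 stage pairs in the fit. The array weights were equal for WT and d1 within a stage (1.27, 0.71, 1.55 and 0.71 at stages 1, 2, 4 and 7), so they weighted stages and not single columns. Beyond this and the fewer genes or columns, the cause was not tested. RGA1 stayed lower in d1 in all alternatives that tested it (log2 -0.32 to -0.38).

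The identifiers OS05G0230501 and OS05G0281400 stayed past the threshold in every alternative run on them. OS05G0206200 and OS10G0492900 kept their direction, and their adjusted p was above 0.05 with no filter (0.051 and 0.12) and without each stage (0.073 to 0.27). The 4 identifiers named for the stage contrast kept direction and call in each refit that gave a stage contrast. The stage count of 5539 was between 3880 and 5656 in the refits, except for 1682 with an absolute log2 change of at least 1.

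Counts without a test moved with the treatment of low values. At stages 1, 2, 4 and 7 the d1 against WT counts of 391, 554, 331 and 420 were 992, 1201, 806 and 898 with a pseudocount of 0.1, and 157, 215, 129 and 178 with a mean of at least 5 FPKM. A lower threshold on the fold gave 1232, 1721, 1154 and 1434, and at least 5 FPKM in a group gave 362 at stage 2 and 220 at stage 4. The stage 7 against stage 1 counts of 2108 in WT and 2069 in d1 were 1039 and 1041 with a mean of at least 5 FPKM and 4270 and 4292 with the lower fold threshold. Leaving the photosynthesis list aside, which was not rerun under these settings, lists with a median outside the central 95% of random lists numbered 1 for genotype, 2 with a pseudocount of 0.1 and 3 after quantile normalization, and 6 for stage in all 3 settings. The cause of these changes was not tested.

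No paired analysis was possible because the columns carry no replicate; this holds for pairing by replicate, while the WT and d1 columns of a stage were paired by the stage block. For the same reason no replicate was left out, and the planned set tests and the test of genotype by stage were not run. The depth is unknown, so no statement rests on it.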

Other observations

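The tests in this part were chosen after the result was seen, except the refit with a mean of at least 5 FPKM and the test of a shift in stage.

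Members of the added lists and of the defence list had differing values in d1 and WT at single stages, where no test was possible, and the members given here were chosen after their values were seen. A clock member had 53.8, 64.2, 83.9 and 201 FPKM in WT at stages 1, 2, 4 and 7, and 58.5, 49.0, 43.3 and 44.1 FPKM in d1 (-0.84 ± 0.36 over the stages, adjusted p = 0.23, limma). A defence member had 18.4 and 29.4 FPKM in WT at stages 4 and 7, and 30.2 and 138 FPKM in d1 (0.79 ± 0.37, adjusted p = 0.26). An abiotic stress member had 0.81, 2.75, 4.57 and 4.80 FPKM in WT and 1.57, 11.4, 0.44 and 0.20 FPKM in d1 (-0.50 ± 0.72, adjusted p = 0.71).

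With a threshold of under 0.1 FPKM in all 4 columns of a genotype and at least 1 FPKM in all 4 of the other, 6 genes qualified, 5 of them on chromosome 5 (Fisher's exact test, two-sided, p = 2.2e-05). Of the 6, 5 had the higher values in d1 and 1 in WT.

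Of the 48 genes called between d1 and WT, 10 were on chromosome 5, where the fullest window of 100 tested genes held 5 calls and ended 159 tested genes before RGA1. Chance placement is argued against, since a share of 0.0044 of 10000 shuffles of the calls over the genes had a window as full. A candidate explanation is a chromosome segment linked to the d1 allele that differs from that of WT, as a strain variant would, but effects of RGA1 loss on these genes were not tested and sequence variants cannot be read from these values. Genes with low values are another, and the refit with a mean of at least 5 FPKM met what that explanation had predicted, with 28 calls on chromosome 5 and 287 elsewhere (odds ratio 1.06, Fisher's exact p = 0.76). That refit called 315 genes, with 44 of the 48 among them, so its odds ratio covers a larger set than the 48. Of the 48 genes, 8 on chromosome 5 and 36 elsewhere had such a mean. The explanation was left open only because of ratios computed after the odds ratio of 1.06 had been seen. These were 2.43 (Fisher's exact p = 0.028) for those of the 48 genes with such a mean and 4.86 (Fisher's exact p = 0.019) for the refit calls with an absolute log2 change of at least 1.

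Photosynthesis genes were higher in some columns than in others. The 12 members went up and down together over the 8 columns, with a median pairwise correlation of 0.66 against 0.24 at the upper end of the central 95% of 1000 random lists. Their highest value in a column ran from 9.36 to 34.1 FPKM, and with no leaf sample used here neither a share of tissue nor the level the meristem itself expresses is known. Genotype as the whole cause is argued against, since the list median was higher in d1 at 2 of the 4 stages and lower at the others. Differing amounts of leaf tissue in the dissected samples stay open beside effects of light, stage or genotype at single stages, because each of these would move the genes together and that they did had been seen before the test.

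The d1 column at stage 2 correlated across genes as closely with WT at stage 1 (r of 0.978) as with WT at stage 2 (0.978). An earlier point of development of the d1 samples could give this, and would make the stage 2 difference run against the change from stage 1 to 7. The correlation across genes was -0.0711 with that change in WT and -0.218 with that in d1. The bound of -0.1 set beforehand for both was passed in d1 and not in WT, so by that rule the prediction of a shift was not met. The other correlations computed were -0.0293 and 0.050 for the stage 4 difference with the change from stage 1 to 7 in WT and d1. For the stage 1 and stage 7 differences with the change from stage 2 to 4 in WT they were -0.00901 and -0.172. A shift was left open only after these values had been seen, because none of them has a spread.

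For the 48 genes called between d1 and WT, the 8 columns were also split into other groups of 4. Of 35 splits, 3 could not be fitted with stage as a block. Of the 32 others, 1 gave as many genes, the real one, and the highest of the rest gave 0. Most of them put both columns of some stages in the same group and estimate the difference from fewer pairs, so they do not settle whether chance is excluded. Only 8 splits part all 4 stage pairs as the real one does, which is too few for a share under 0.05; the real split gave 48 genes and the highest other 0.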
